A study of Mus musculus with 6 samples.

How the data were processed

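RNA of sorted dendritic cells was measured in 6 libraries of C57BL/6 mice that lacked a Rag gene, and therefore their own T and B lymphocytes, and were kept free of microbes. The libraries cross 2 tissues, peripheral lymph node and spleen, with 3 states: mice left un-injected, mice given naive CD4 T cells and mice given regulatory T cells (Treg), both sampled 1 week after the transfer. Each of the 6 groups holds 1 library. Per the labels' protocols the dendritic cells were isolated by flow cytometry, RNA was taken up in Trizol and libraries were made with an Illumina TruSeq RNA kit from total RNA. The gate, the number of mice per library, their sex and whether a lymph node and a spleen library come from the same animals are not given in the sources used here.

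The authors deposited 1 table of all 6 libraries with values scaled by gene length and by library, which are treated here as FPKM (fragments scaled by gene length and by library). The header does not name the unit; FPKM was taken from the values, which are fractional, sum to a different total in each library and, for low genes, take ratios between libraries that pile up at 1 value and its multiples. RSEM, edgeR 3.16.5, mm10 and GRCm38.p4 are named per the submitters' processing notes, with no role for any of them. The authors also deposited 6 tables of comparisons of 1 library against another, with a log2 fold change, a p-value and a q-value per locus, per the file headers; they mark loci at 2-fold or more with a p-value of 0.01 or less. Which tool gave those values is not given in the sources used here.

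The table has 21958 lines and 21914 gene symbols. The values of the 38 symbols with several lines were summed. A gene was kept where it reached 1 FPKM in at least 2 of the 6 libraries, which left 10818 genes. Of 21688 Ensembl identifiers in the table that the GENCODE M21 annotation of GRCm38 holds, 485 (2.24%) lie away from the locus on their own line, where they belong to another gene, whereas 21288 of 21298 symbols overlap their locus, among them every gene of the lists. Genes were therefore taken by symbol, and identifiers and coordinates from the annotated gene of that name at that locus. Of 13 mitochondrial genes 11 are listed at 0 in all 6 libraries, so a 0 in the table can be a missing estimate and no fold is given against a library at 0. Reads of near-identical genes (Tgtp1 and Tgtp2, Ifit3 and Ifit3b, the globin genes) or of overlapping genes (Igtp and Irgm2) can be split between them in a way the table does not show.

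The deposited values hold no counts and the depth of the libraries is not given. From the steps between low values of genes of 800 to 2500 bases, 1 fragment per kilobase was estimated to stand for 0.463 to 0.737 FPKM, the most in the un-injected lymph node library; no counts, counting intervals or detection limits were derived from it. The sums of the values were 677612, 622680 and 552580 in the un-injected, naive and Treg lymph node libraries and 861260, 655903 and 657560 in the spleen libraries, and the median-ratio factors between libraries lay between 0.9863 and 1.0292, so the values were used on the scale as deposited. Low values rest on few fragments, which is why named genes had to reach 5 FPKM.

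The test across libraries was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(FPKM + 1), in an additive model of transfer and tissue over all 6 libraries, with Benjamini-Hochberg adjustment at 0.05. It leaves 2 residual degrees of freedom, so its p-values measure how far the tissues agree in their response, not the spread between mice. The plan named a count test; since the deposited values are not counts, limma took its place, and neither the DESeq2 test nor the edgeR alternatives were run. Within a tissue no test was made: the log2 ratio of FPKM + 0.5 of 2 libraries is given, a fold is that ratio on the linear scale, and both understate the change of low genes. There is no replicate check of such a difference. Adjusted p-values below are from limma.

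Before the data were examined, 38 gene lists were written down, of dendritic cell activation, antigen presentation, cytokine response, metabolism, cell state and the markers of dendritic cell subsets and other cell types. They hold 677 genes, 665 in the table and 543 past the filter. For each list the median log2 ratio is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries; a list stood apart where the percentile was under 2.5 or over 97.5. The count of list genes past limma's threshold is given over all genes and adjusted over the list alone. fry, the rotation test of limma, asked of 36 lists whether their genes move, on balance, 1 way, and in its mixed form whether they change in either direction. Also fixed before the data were examined were the model, the filter, the alternatives and the rule for named genes. That rule takes for each transfer comparison the 10 genes in each direction with the largest smaller-of-both-tissues log2 ratio among those at 2-fold or more in both tissues and at 5 FPKM or more in the higher library of each tissue (in place of 20 counts); up to 4 members of each list by the same measure; the 10 genes in each direction with the largest fold among those past the tissue test; the 5 genes with the largest opposite naive effect in the tissues; and a fixed set of 16 genes given in every library. Predicted genes and pseudogenes known by a number alone are not named.

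Simulated data with the real residual spread and 200 changed genes among 10818 were used to test the limma step for naive against un-injected: of 50 genes each at 2-, 4-, 8- and 16-fold, 0%, 10%, 36% and 64% were recovered, with 0 false calls. At 0.25 of that spread 82%, 88%, 100.0% and 100.0% were recovered, with 6 false calls among the genes not changed. A shift of 1.5 (log2) planted in 1 list gave percentile 100.0, and 5.2% of 210 values of other lists fell outside the range. The alternatives were median-ratio factors and library totals as scalings, no filter and a filter at 5 FPKM, other pseudocounts, no block term, the authors' fold changes and leaving out each library. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.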

Results

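The data are gene expression levels of flow-sorted dendritic cells, the antigen-presenting cells that activate T cells, from germ-free mice without T and B lymphocytes of their own. The 6 libraries are 1 each from peripheral lymph node and spleen of un-injected mice, of mice given naive CD4 T cells 1 week earlier and of mice given Treg. Between 9936 and 10383 genes reached 1 FPKM per library, and the 10 highest genes held 12.03% to 16.73% of the summed values. The title of the series places the study in the activation of antigen-presenting cells by T cells that breaks tolerance to self, so the comparisons ask what naive T cells and Treg each did to the dendritic cells of both tissues. Each group had 1 library, so no value within a group has an error, and the errors below are standard errors of the model over both tissues.

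The sorted cells carried dendritic cell transcripts in all 6 libraries. Itgax, the CD11c integrin chain, stood at 39.7, 196 and 134 FPKM in the un-injected, naive and Treg lymph node libraries and at 305, 377 and 385 FPKM in the spleen libraries. Zbtb46, a transcription factor of conventional dendritic cells, lay between 13.5 and 49.8 FPKM, and Flt3, the receptor for the growth factor of these cells, between 56.6 and 221 FPKM. The recombinase gene Rag1 reached at most 0.0842 FPKM and Rag2 at most 0.225 FPKM. Genes of the T cell list ranged from a listed 0, which can be a missing estimate, to 93.7 FPKM. Cd3e was at 0.584 FPKM in the un-injected lymph node library and listed at 0 in the other 5, Cd28 reached at most 0.801 FPKM, Foxp3 at most 0.72 FPKM, and Cd40lg was listed at 0 in all 6. Cd4, which some dendritic cells also express, lay between 4.91 and 13.2 FPKM in lymph node and between 19.6 and 47.6 FPKM in spleen. Tcf7, a transcription factor of T and other lymphoid cells, was at 93.7, 20.7 and 60.2 FPKM in the un-injected, naive and Treg lymph node libraries and at 4.496, 10.4 and 6.33 FPKM in spleen. Il7r, the interleukin 7 receptor chain, was at 68.7, 14.005 and 62.1 FPKM and at 3.46, 3.72 and 2.64 FPKM, and Ms4a4b reached 18.9 FPKM in the naive lymph node library. Ctla4, the inhibitory receptor for CD80 and CD86, lay between 0.436 and 9.85 FPKM. Ifng, which encodes interferon-gamma, was listed at 1.31 FPKM in the naive lymph node library, at 0.445 FPKM in the Treg lymph node library and at 0 in the others. Of the T cell list 10 of 23 genes passed the filter, and its median log2 ratio of naive to un-injected was -0.03 in lymph node and -0.33 in spleen, and above 0 in both with library totals.

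Dendritic cells of mice given naive T cells had higher levels of interferon response genes than those of un-injected mice in both tissues. The 28 measured interferon-gamma response genes had a median log2 ratio of 2.45 in lymph node and 1.66 in spleen, at percentile 100 of random lists in both, and the 30 type I interferon response genes 3.39 and 0.97, also at percentile 100 in both. Igtp, an immunity-related GTPase against intracellular pathogens, went from 6.23 to 141 FPKM in lymph node and from 5.11 to 22.9 FPKM in spleen. Gbp2, a guanylate-binding protein of the same defence, went from 174 to 660 FPKM in lymph node and from 14.7 to 80.2 FPKM in spleen. Cxcl10, a chemokine that draws activated T cells, went from 60.3 to 1069 FPKM in lymph node and from 52.1 to 153 FPKM in spleen.

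Adjusted over the list alone, 18 of the 28 interferon-gamma response genes rose with naive T cells. Over all genes 0 of them passed. They include the GTPases Igtp, Irgm1, Ifi47, Iigp1, Tgtp1 and Gbp2 and the chemokines Cxcl9 and Cxcl10. Of the type I list 17 of 30 rose adjusted over the list alone and 0 over all genes, among them Isg15, a ubiquitin-like protein, Rsad2, the antiviral protein viperin, and Oas2, Oas3 and Oasl2 of the oligoadenylate synthetase family. At least 2-fold higher in both tissues were 15 of the interferon-gamma genes, where random lists held at most 5, and 15 of the type I genes, where random lists held at most 4. Without the tissue term the count for the interferon-gamma list was 1. For the type I list it was 10 without the un-injected lymph node library, 27 without the un-injected or the naive spleen library and 26 with library totals. The fry test of limma over 36 lists gave an adjusted p of 0.528 for interferon-gamma response genes and 0.87 for type I interferon response genes, and for changes in either direction 0.426 and 0.755.

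Of the genes with the largest smaller-of-both ratios, Tgtp1 was 6.75-fold higher with naive T cells in lymph node and 5.21-fold in spleen (model log2 difference 2.42 ± 0.44), Iigp1 39.4-fold and 4.86-fold (3.45 ± 0.71), and Ifi47 24.0-fold and 4.12-fold (3.26 ± 0.61). Irgm1 was 17.7-fold and 3.9-fold higher (3.01 ± 0.54). Irgm2, which overlaps Igtp on the same strand of chromosome 11, was 8.75-fold and 3.74-fold higher. Pydc4, of a family of pyrin-domain proteins, was 35.1-fold and 4.53-fold higher. Oas2 went from 3.0 to 45.2 FPKM in lymph node and from 4.24 to 17.4 FPKM in spleen. Plau, the urokinase plasminogen activator, went from 2.38 to 34.0 FPKM and from 0.916 to 5.17 FPKM. Lower with naive T cells in both tissues were Clu, an extracellular chaperone, at 687 against 28.7 FPKM in lymph node and 5.63 against 0.571 FPKM in spleen, and Cd207, the Langerhans cell lectin langerin, at 15.5 against 2.23 FPKM and 45.6 against 8.06 FPKM. Ephx1, an epoxide hydrolase, went from 53.1 to 3.67 FPKM in lymph node and from 10.1 to 2.01 FPKM in spleen, and Idh1, the cytosolic isocitrate dehydrogenase, from 118 to 24.2 FPKM and from 18.7 to 4.77 FPKM. The other 6 lower genes under the naming rule were Slc22a18, Rab38, Lzic, Tm4sf5, Cbr4 and Umad1, with model log2 differences between -2.35 and -1.70. Each of the 20 genes taken by the size of both ratios, Igtp and Gbp2 among them, had an adjusted p of 0.661.

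The genes lie at these places on mm10: Igtp (ENSMUSG00000078853) on chromosome 11 from 58199556 to 58207591, Irgm1 (ENSMUSG00000046879) on chromosome 11 from 48861968 to 48871683, Tgtp1 (ENSMUSG00000078922) on chromosome 11 from 48985327 to 48994172, and Ifi47 (ENSMUSG00000078920) on chromosome 11 from 49076587 to 49096974. Gbp2 (ENSMUSG00000028270) lies on chromosome 3 from 142620602 to 142638008, Iigp1 (ENSMUSG00000054072) on chromosome 18 from 60376027 to 60392634, Cxcl10 (ENSMUSG00000034855) on chromosome 5 from 92346638 to 92348889, Clu (ENSMUSG00000022037) on chromosome 14 from 65968483 to 65981547, and Cd207 (ENSMUSG00000034783) on chromosome 6 from 83671215 to 83677857.

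In lymph node the maturation program, the genes dendritic cells switch on as they mature and migrate, was lower in the naive library. Its 26 measured genes had a median log2 ratio of -2.28 at percentile 0.0, and 24 were at least 2-fold lower, whereas in spleen the median was -0.03 at percentile 96.4, and above 0 with either other scaling. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 5829 FPKM in the un-injected lymph node library, 895 FPKM in the naive library and 2427 FPKM in the Treg library, against 356, 508 and 312 FPKM in spleen. The list of Langerhans and migratory dendritic cells moved with it, with a median of -2.55 in lymph node and 0.25 in spleen. In the model, which averages the tissues, all 26 maturation genes had a negative difference. Only 15 were lower in both tissues, and 11 were higher in spleen. In the model 3 maturation genes (Ccl17, Cst3 and Laptm4b) fell adjusted over the list alone, against 0 over all genes (fry adjusted p = 0.87 for the dendritic cell maturation program). The CD40 and NF-kB target genes had medians of -1.29 in lymph node and 0.15 in spleen, and the costimulatory and coinhibitory ligands -0.63 and 0.32. The 18 chemokine genes had medians of 0.45 and -0.66, and adjusted over the list alone Ccl3 and Cxcl10 rose while Ccl17 and Ccl8 fell, with 0 over all genes. The chemokine list did not pass fry: for naive against un-injected 1 of 36 lists, adipocytes, reached an adjusted p of 0.05 in a common direction. For changes in either direction 0 did. Among the ligands of CD28, Cd80 was at 113 and 93.0 FPKM in the un-injected and naive lymph node libraries and at 88.9 and 108 FPKM in spleen, and Cd86 at 98.3 and 140 FPKM and at 256 and 205 FPKM.

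Monocyte genes were higher in the naive lymph node library and lower in the naive spleen library. The 17 monocyte genes had a median log2 ratio of 3.90 in lymph node, where 16 were at least 2-fold higher, and -1.32 in spleen, where 9 were at least 2-fold lower. In lymph node the monocyte list was thus higher beside the interferon lists, and in spleen it was lower while the interferon lists were higher. The list was lower in the Treg spleen library too, at -0.75. Both spleen ratios share the un-injected spleen library, which was high in neutrophil genes. S100a8 was at 318 FPKM there, against 9.33 FPKM in the naive and 1.59 FPKM in the Treg spleen library. The fall against un-injected in spleen thus cannot be told apart from a property of that library. The monocyte median of naive to Treg, which leaves it out, was -0.43 in spleen. The 5 genes with the largest opposite ratios in the tissues include Ly6c2, a surface protein of inflammatory monocytes, at 7.51 against 1119 FPKM in lymph node and 59.9 against 10.99 FPKM in spleen, and Chil3, a chitinase-like protein of monocytes and macrophages, at 1.48 against 160 FPKM and 71.8 against 3.60 FPKM. The others were Clec4e, Hp and Apoc2, the last listed at 0 in the un-injected lymph node library. Toll-like receptors and their adaptors had medians of 2.01 and 0.07, glycolysis genes 1.49 and -0.36 (above 0 in spleen with library totals), endocytic and C-type lectin receptors 2.47 and -0.83, genes of type 2 conventional dendritic cells 1.87 and 0.17, and those of type 1 conventional dendritic cells 1.27 and -0.91. MHC class II presentation genes had medians of 0.96 and -0.20 (above 0 in spleen with library totals), MHC class I presentation genes -0.28 and 0.06, and neutrophil genes 1.41 and -3.65. With Treg, lymph node MHC class II was at 0.86, endocytic receptors at 0.94, and type 1 and 2 cells at 0.96 and 0.67. Both ratios share the un-injected library. Medians of naive to Treg, which leave it out, were 0.12 for MHC class II, 0.07 for endocytic receptors, and -0.195 and 0.07 for the subsets. The rise of these lists cannot be told apart from a property of that library. Toll-like receptors were at 0.96 with Treg and 1.09 for naive to Treg, glycolysis at 0.07 and 1.15. The neutrophil value in lymph node rests on low values. The median level of the list was 1.48 FPKM in the un-injected and 1.39 FPKM in the naive library, and 6 genes were higher and 4 lower. Ribosomal protein genes were lower in 25 of 25 cases in both tissues, with medians of -0.44 and -0.65. The lymph node median, at percentile 2.76, did not stand apart. The spleen median was at percentile 0.02, where the central range of random lists also lay below 0, from -0.53 to -0.16.

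Over all genes the limma test of naive against un-injected called 0 of 10818, with 785 at an unadjusted p under 0.05 and a smallest adjusted p of 0.661. It called 249 genes without the un-injected spleen library and 425 without the naive spleen library. At 2-fold or more, 1829 genes were higher and 1798 lower in lymph node, and 487 higher and 650 lower in spleen. In spleen 42.8% of these genes were higher, against 77.2% with library totals, which move the median of all genes by 0.35. At least 2-fold higher in both tissues were 131 genes, where 82.3 would be expected of independent tissues, and 143 were lower in both, where 108.0 would be expected. Another 189 were higher in lymph node and lower in spleen, where 109.9 would be expected, and 107 the reverse, where 80.9 would be expected. Of the 38 lists 5 stood apart from random lists the same way in both tissues, both interferon lists, genes linked to tolerance and type 2 conventional dendritic cell genes above and adipocyte genes below, and 10 stood apart in opposite ways.

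In the Treg libraries the medians of the chemokine and proinflammatory cytokine lists lay below those of the un-injected libraries in both tissues, while few of their genes passed a test. The 18 chemokine genes had median log2 ratios of -1.01 and -0.79 at percentile 0.0 in both, and the 14 proinflammatory cytokine genes -0.83 and -0.53 at percentiles 0.03 and 0.79. Adjusted over the list alone 1 of the 18 chemokines and 0 of the 14 cytokines passed, and over all genes 0 of either. The fry test gave an adjusted p of 0.877 for chemokines and for proinflammatory cytokines. In spleen the chemokine list was also low with naive T cells, at -0.66 and percentile 0.0, and its median of naive to Treg was 0.0 there. The cytokine list was at -0.04 in the naive spleen library. The migratory list, which holds Ccl17 and Ccl22, was lower with Treg in both tissues too, at -0.99 and -0.48. Genes of other cells were also lower in the Treg spleen library than in the un-injected one, with medians of -3.92 for neutrophils, -0.90 for macrophages and -1.27 for natural killer and innate lymphoid cells, against 0.0, 0.46 and 0.65 in lymph node. The same lists were lower in the naive spleen library, at -3.65, -0.99 and -1.59, and both ratios share the un-injected spleen library. Ccl22, a chemokine that attracts Treg through the receptor CCR4, went from 2051 to 523 FPKM in lymph node and from 33.7 to 5.601 FPKM in spleen, and Ccl17, its sister ligand, from 438 to 93.4 FPKM and from 12.9 to 3.62 FPKM. Il12b, a subunit of interleukins that drive helper T cell responses, went from 255 to 85.7 FPKM and from 67.7 to 25.5 FPKM, and Cd40, the receptor for T cell help, from 450 to 197 FPKM and from 91.3 to 45.1 FPKM.

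The interferon lists showed less of a difference with Treg than with naive T cells. The interferon-gamma list had a median log2 ratio of -0.22 in lymph node (above 0 with library totals) and 0.06 in spleen, at percentiles 10.1 and 92.0, and the type I list 0.59 at percentile 100 and -0.04 at percentile 64.3 (above 0 with library totals). Adjusted over the list alone, 0 genes of either interferon list passed, and 1 of the interferon-gamma list did without the un-injected spleen library. The 1 chemokine that passed over the list alone was Ccl17 (model log2 difference -1.91 ± 0.30). Of the 26 maturation genes all had a negative model difference on the deposited scale, though not with library totals. In both tissues 19 were lower, and 7 were higher in spleen. Ccl17 and Cst3, the cystatin C gene, fell adjusted over the list alone, against 0 over all genes (fry adjusted p = 0.877 for the dendritic cell maturation program). The median log2 ratio of the maturation list was -1.15 in lymph node and -0.22 in spleen (above 0 with library totals), and the migratory list had medians of -0.99 and -0.48. Il6 went from 17.7 to 9.18 FPKM and from 17.8 to 2.11 FPKM, and Il15, a cytokine for natural killer and memory T cells, from 181 to 87.3 FPKM and from 18.0 to 7.87 FPKM. The costimulatory and coinhibitory ligands had medians of -0.98 and -0.26 (above 0 in spleen with library totals), with Cd80 at 53.3 FPKM and Cd86 at 78.7 FPKM in the Treg lymph node library and at 87.7 and 175 FPKM in the Treg spleen library. MHC class I presentation genes had medians of -0.69 at percentile 0.02 and -0.32 at percentile 82.3. The spleen value thus lay inside the range of random lists, and was also above 0 with library totals. The monocyte list had medians of 1.68 and -0.75.

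The list of immediate early and heat shock genes went both ways with Treg, with medians of 0.36 and 0.54 at percentiles 99.2 and 100. In spleen it was also higher with naive T cells, at 0.32 and percentile 99.97, and both ratios share the un-injected spleen library. Its median of naive to Treg there was -0.25. With Treg 12 of its 19 genes were higher in lymph node and 15 in spleen. In both tissues 2 were at least 2-fold higher and 2 at least 2-fold lower, and 0 passed over the list alone or over all genes. For immediate early and heat shock genes the fry adjusted p was 0.498 for a common direction and 0.0285 for changes in either direction, the latter 0.256 to 0.991 on leaving out any 1 library. The 2 lower genes encode heat shock proteins of the 70 kDa family, Hspa1a, from 11.498 to 4.62 FPKM in lymph node and from 1.35 to 0.319 FPKM in spleen, and Hspa1b, from 7.96 to 3.24 FPKM and from 2.79 to 0.694 FPKM. Egr1, an early growth response transcription factor, went from 32.1 to 104 FPKM in lymph node and from 40.1 to 88.1 FPKM in spleen, Egr3 from 1.01 to 14.1 FPKM and from 19.9 to 41.0 FPKM, and Nr4a1, an orphan nuclear receptor, from 164 to 462 FPKM and from 501 to 926 FPKM. The Y-linked genes Ddx3y and Eif2s3y were at 36.9 and 58.3 FPKM in the Treg lymph node library and at 52.4 and 39.5 FPKM in the Treg spleen library, where the other 4 libraries had at most 0.44 FPKM of either. Both had an adjusted p of 0.0573 over all genes, and 4 of the 4 sex-linked genes measured rose adjusted over the list alone, these with Kdm5d and Uty, which are named here after their values were seen (fry adjusted p = 0.00847 for sex-linked genes, and 0.0886 to 0.441 on leaving out any 1 of the other 4 libraries). Ddx3y (ENSMUSG00000069045) lies on chromosome Y from 1260771 to 1286629 and Eif2s3y (ENSMUSG00000069049) from 1010543 to 1028847.

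Among the other genes under the naming rule, Fkbp5, an immunophilin that binds the glucocorticoid receptor complex, was 2.98-fold higher with Treg in lymph node and 2.62-fold in spleen (1.44 ± 0.29), and Myc, a growth-promoting transcription factor, 5.51-fold and 2.37-fold (1.62 ± 0.40). BC021614 was 5.0-fold and 4.54-fold higher. Srgap1, Stra6l, Prr3, Rsc1a1 and Clcf1 lay between 2.39-fold and 3.52-fold higher in each tissue. S100a9, a calcium-binding protein abundant in neutrophils, was at 11 FPKM in the un-injected and listed at 0 in the Treg lymph node library. In spleen it went from 351 to 2.32 FPKM, and the naive spleen library was also low, at 12.8 FPKM. It fell adjusted over the list alone, the 1 such gene of 10 neutrophil genes. In the fry test of 1 common direction, sex-linked genes were the 1 list of 36 to reach an adjusted p of 0.05 for Treg against un-injected. Slpi, a secreted protease inhibitor, was at 5.88 FPKM and listed at 0 in lymph node and went from 119 to 22.5 FPKM in spleen, and Ccl24, an eosinophil-attracting chemokine, from 16.5 to 3.15 FPKM and from 7.17 to 0.416 FPKM. Clu went from 687 to 209 FPKM in lymph node and from 5.63 FPKM to a listed 0 in spleen. Mras, Pdlim4, Umad1 and Insl6 had model log2 differences between -1.97 and -1.42. Each gene outside the Y chromosome had an adjusted p of 0.938.

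The limma test of Treg against un-injected called 0 of 10818 genes, with 508 at an unadjusted p under 0.05. It called 2 with a pseudocount of 2 FPKM, 2 without the naive lymph node or the naive spleen library, 4 without the un-injected lymph node library and 42 without the un-injected spleen library. At 2-fold or more, 1233 genes were higher and 747 lower in lymph node, and 488 higher and 635 lower in spleen. The share of higher genes was 62.3% in lymph node and 43.5% in spleen, against 82.3% and 80.2% with library totals, which move the median of all genes by 0.26 and 0.34. At least 2-fold higher in both tissues were 86 genes, where 55.6 would be expected of independent tissues, and 131 were lower in both, where 43.8 would be expected. Another 107 were higher in lymph node and lower in spleen, where 72.4 would be expected, and 34 the reverse, where 33.7 would be expected.

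Set directly against each other, the naive libraries had higher interferon response genes than the Treg libraries in both tissues. The interferon-gamma list had a median log2 ratio of 2.56 in lymph node and 1.51 in spleen, with 28 of 28 genes positive in the model, and the type I list 2.88 and 1.08, with 30 of 30 positive on the deposited scale, though not with library totals. Beside them the monocyte list was higher in lymph node, at 2.35, and lower in spleen, at -0.43. Gbp2 was 7.11-fold higher in lymph node and 7.91-fold in spleen (2.87 ± 0.28, adjusted p = 0.313), Cxcl10 43.5-fold and 5.12-fold (3.88 ± 0.75), and Zbp1, a sensor of Z-form nucleic acids, 12.8-fold and 4.83-fold (2.96 ± 0.55). Ly6a, the Sca-1 surface protein that interferons induce, was at 1065 against 63.0 FPKM in lymph node and 103 against 16.0 FPKM in spleen. Cd274, which encodes the inhibitory ligand PD-L1, was at 247 against 126 FPKM and 86.2 against 38.7 FPKM. Y-linked genes stood out in both Treg libraries, so the sex of the mice may differ along with the transfer in this comparison.

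Adjusted over the list alone, 16 of 28 interferon-gamma response genes and 19 of 30 type I genes were higher with naive T cells than with Treg, and 0 of either over all genes. At least 2-fold higher in both tissues were 18 and 17 of them, where random lists held at most 5 and 4. The interferon-gamma count was 0 without the Treg lymph node library and 0 without the tissue term. The type I count was 0 without the naive lymph node library or either Treg library, 0 without the tissue term and 12 with no filter. The fry test of limma gave an adjusted p of 0.467 for interferon-gamma response genes and 0.735 for type I interferon response genes, and for changes in either direction 0.206 and 0.713.

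Other genes with the largest naive excess over Treg included Cfb, complement factor B, at 42.3-fold and 5.22-fold, Tgtp2, a near copy of Tgtp1, at 8.9-fold and 6.73-fold, and Igtp at 16.9-fold and 4.68-fold. Iigp1 and Serpina3f, a serine protease inhibitor, were at 61.2 and 35.6 FPKM in the naive lymph node library against 1.22 and 1.28 FPKM with Treg, and listed at 0 in the Treg spleen library. S100a8, the partner of S100a9, was at 9.45 FPKM and listed at 0 in lymph node, and at 9.33 and 1.59 FPKM in spleen. Lower with naive T cells than with Treg were Ddx3y and Eif2s3y (adjusted p = 0.0506 each), and Fgfr1, a fibroblast growth factor receptor, at 3.57 against 27.5 FPKM in lymph node and 9.91 against 35.3 FPKM in spleen. Sult1a1, a sulfotransferase, was at 4.19 against 29.8 FPKM and 10.9 against 46.6 FPKM, and Fkbp5 at 9.68 against 28.5 FPKM and 12.5 against 39.9 FPKM. Rsc1a1, Hddc3, Zfp788, Slc26a6 and Rnf150 had model log2 differences between -2.63 and -1.43. Apart from Gbp2 and the Y-linked pair, each of the 20 genes had an adjusted p of 0.963.

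Genes linked to tolerance had median log2 ratios of naive to Treg of 0.80 in lymph node and 0.36 in spleen, at percentiles 99.97 and 99.8. Of the 18 measured, 0 passed over the list alone or over all genes. At least 2-fold higher in both tissues was 1, where random lists held up to 6, and Cd274 is also in the interferon-gamma list. Immediate early and heat shock genes were at -0.40 and -0.25, and dendritic cell core genes at -0.78 and -0.13, all under percentile 2.5. Maturation genes were lower in lymph node at -1.10 and higher in spleen at 0.36. Oxidative phosphorylation genes had medians of 0.71 and 0.18, and the monocyte list 2.35 and -0.43. The limma test called 0 of 10818 genes, with 370 at an unadjusted p under 0.05. It called 2 with a pseudocount of 2 FPKM or without the naive lymph node library, 4 without the un-injected lymph node or the un-injected spleen library and 134 without the naive spleen library. At 2-fold or more, 1006 genes were higher and 1233 lower in lymph node, and 446 higher and 401 lower in spleen; the share of higher genes in lymph node was 44.9%, against 33.1% with library totals, which move the median of all genes by -0.16, 51.1% with a filter at 5 FPKM and 52.5% with a pseudocount of 2 FPKM. Both tissues had 150 genes at least 2-fold higher, where 41.5 would be expected of independent tissues, and 98 lower, where 45.7 would be expected. Another 48 were higher in lymph node and lower in spleen, where 37.3 would be expected, and 62 the reverse, where 50.8 would be expected.

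**Figure D1:**
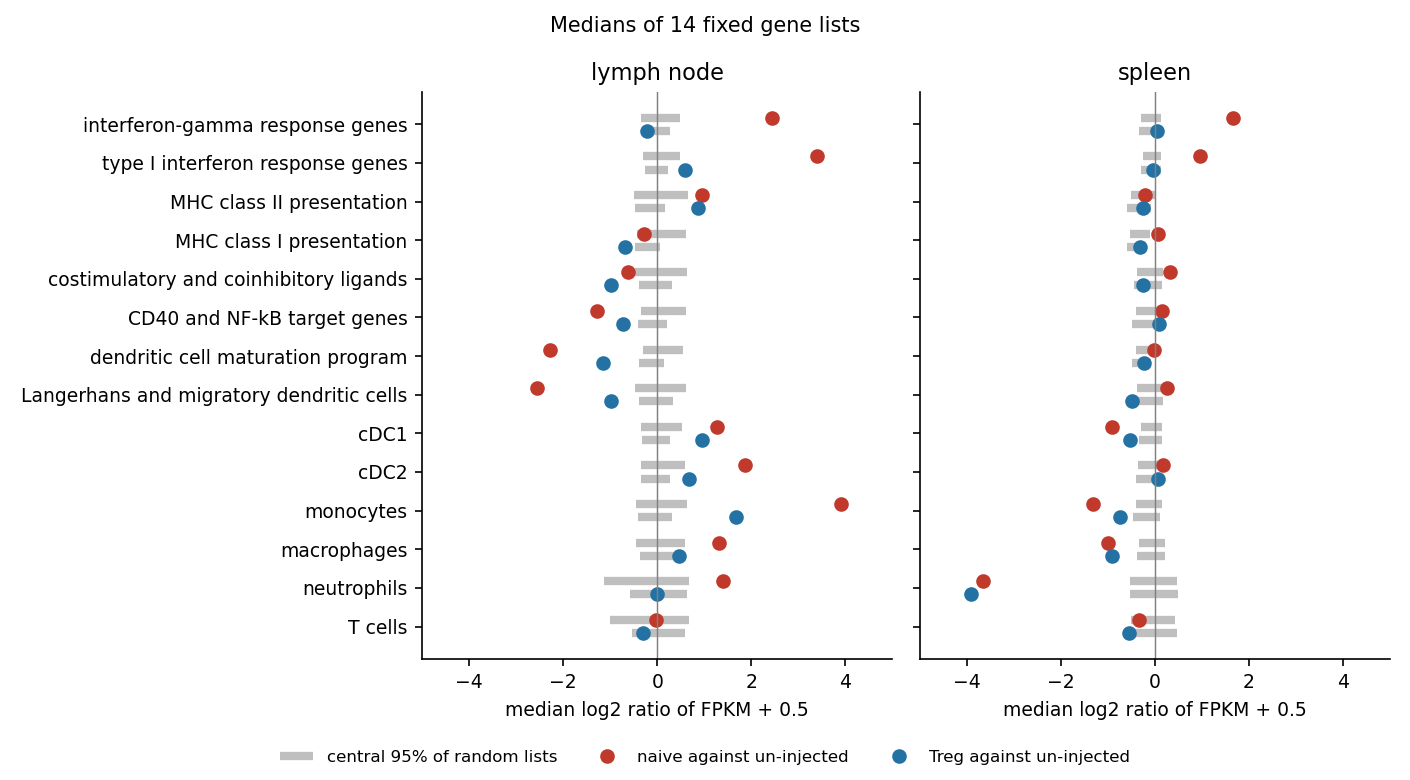
Median log2 ratios of FPKM + 0.5 for 14 gene lists in lymph node and spleen, naive over un-injected in red and Treg over un-injected in blue, with grey bars for the central range of 10000 random lists. With naive T cells the interferon-gamma list lies at 2.45 in lymph node and 1.66 in spleen, and the monocyte list at 3.90 and -1.32.

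**Figure D2:**
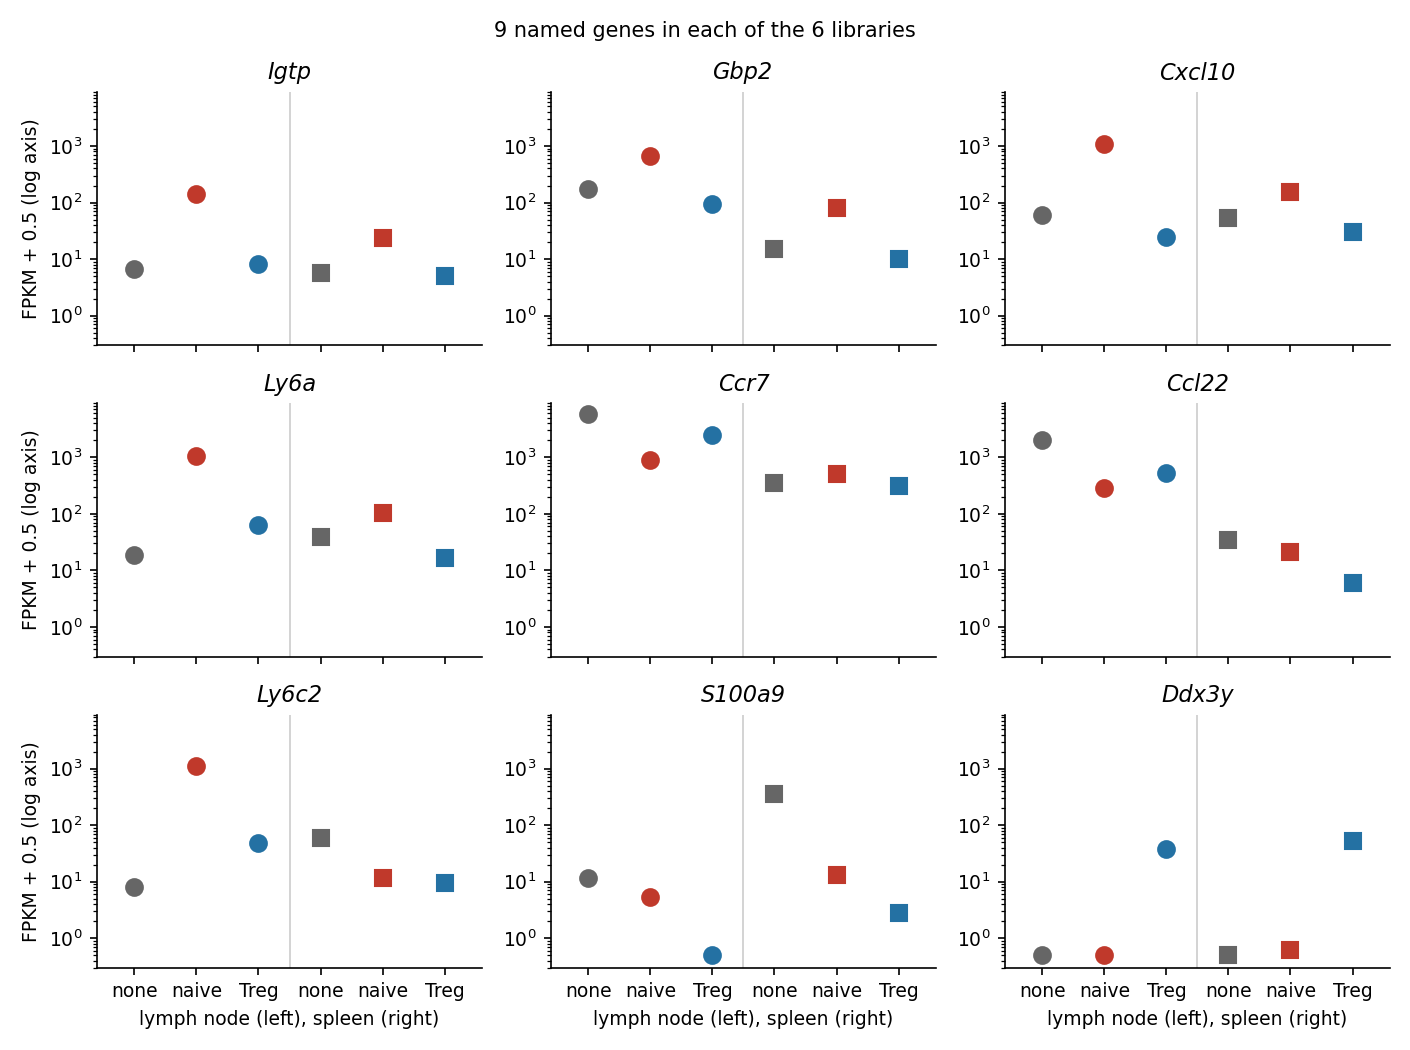
FPKM + 0.5 on a log axis for 9 genes in each of the 6 libraries, circles for lymph node and squares for spleen, un-injected in grey, naive in red and Treg in blue. Gbp2 is highest in the naive library of each tissue (660 and 80.2 FPKM), and Ddx3y stands out in both Treg libraries (36.9 and 52.4 FPKM).

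Dendritic cells of the lymph node differed from those of the spleen in chemokine, maturation and migration genes, most of them higher in lymph node. As whole lists these did not pass the fry test of 1 common direction. Ccl22 was 5.31 ± 0.53 higher on the log2 scale (adjusted p = 0.0429), Ccl17 4.69 ± 0.25 (adjusted p = 0.0222) and Ccl8, a chemokine for monocytes and T cells, 4.75 ± 0.26 (adjusted p = 0.0222), each higher in 3 of 3 transfer states. Clu was higher by 6.22 ± 0.66 and Il15ra, which presents interleukin 15 to other cells, by 3.98 ± 0.38. In spleen Cadm1, an adhesion molecule of type 1 conventional dendritic cells, was higher (lymph node minus spleen -2.96 ± 0.28), at 38.7 to 76.6 FPKM against 2.59 to 9.31 FPKM.

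Of 10818 genes 74 passed limma's tissue test, 48 higher and 26 lower in lymph node, with 2738 at an unadjusted p under 0.05. Adjusted over the list alone, 23 of 26 maturation genes passed, 5 of them over all genes, and 25 of the 26 were higher in lymph node. All 17 migratory genes passed adjusted over the list alone and 4 over all genes, with 15 of the 17 higher in lymph node. Of the chemokines 12 of 18 passed over the list alone and 6 over all genes, of the CD40 and NF-kB target genes 13 of 20 and 0, of the MHC class I genes 11 of 20 and 0, and of the costimulatory and coinhibitory ligands 10 of 16 and 2. Higher in spleen were proliferation genes, with 22 of 25 passing over the list alone, 0 over all genes and all 25 lower in lymph node, and ribosomal protein genes, with 25 of 25, 0 and all 25 lower. Type 1 conventional dendritic cell genes passed in 18 of 25 cases over the list alone and 1 over all genes, with 21 lower in lymph node, and MHC class II genes in 9 of 17 and 1, with 14 lower. In the fry test of 1 common direction no list reached an adjusted p of 0.05 between the tissues with all 6 libraries, and 1 did without either un-injected library. With all 6 it was 0.132 for chemokines, 0.164 for MHC class I presentation and ribosomal proteins, and 0.167 for the dendritic cell maturation program, for Langerhans and migratory dendritic cells and for proliferation. For changes in either direction 17 of 36 lists reached 0.05 with all 6 libraries, and 0 on leaving out any 1 library, with an adjusted p of 0.0186 for chemokines and macrophages, 0.0406 for Langerhans and migratory dendritic cells, 0.0466 for the dendritic cell maturation program, MHC class I presentation and ribosomal proteins, and 0.00491 for T cells.

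The other genes named as higher in lymph node were Mmp25, a membrane-bound metalloproteinase, at 55.5 to 172 FPKM against 2.01 to 3.161 FPKM in spleen, Ltc4s, the leukotriene C4 synthase, at 6.59 to 159 FPKM against at most 2.84 FPKM, and Nrp2, a semaphorin receptor, at 18.4 to 47.1 FPKM against 0.393 to 0.958 FPKM. Nudt17 and Slc27a3 were higher by 4.64 and 4.39 on the log2 scale. Higher in spleen were Hbb-bt, a beta-globin gene with near-identical copies, at 11.3 to 42.2 FPKM against at most 0.795 FPKM, Gp2, a glycoprotein that binds bacterial fimbriae, at 10.6 to 35.9 FPKM against at most 0.237 FPKM, and Mmp12, the macrophage elastase, at 52.1 to 85.8 FPKM against 3.35 to 12.7 FPKM. Asb2, Fcrl1, Ppp1r14a, Adgrl3, Fcna and Pdia5 lay between -3.69 and -3.06 on the log2 scale. The erythroid and platelet list, to which the globin gene belongs, passed in 6 of 10 cases over the list alone, with 8 of 10 lower in lymph node. Ccl22 (ENSMUSG00000031779) and Ccl17 (ENSMUSG00000031780) lie on chromosome 8 from 94745590 to 94751699 and from 94810453 to 94812036, and Ccl8 (ENSMUSG00000009185) on chromosome 11 from 82115185 to 82116799.

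The count of 74 depended on the setting: it was 23 with library totals, 22 with a filter at 5 FPKM, 38 with a pseudocount of 2 FPKM, 0 with no filter and 311 without the transfer term. It was 281 and 299 without the un-injected lymph node or spleen library, 1555 and 1557 without the naive libraries, and 0 without either Treg library.

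The transfer effects showed little relation between the tissues across the 10818 genes, which are not independent replicates. Pearson's r between lymph node and spleen was -0.057 for naive against un-injected (Spearman -0.064), 0.096 for Treg against un-injected (0.098) and 0.2 for naive against Treg (0.156). The lymph node naive effect and the spleen Treg effect had r = -0.115, and the lymph node Treg effect and the spleen naive effect r = -0.002. Within a tissue both effects share the un-injected library, and the naive and Treg effects had r = 0.686 in lymph node and 0.63 in spleen. Simulated groups with no effect gave 0.498, a value that the shared library fixes for groups of equal spread. The covariance was 0.769 in lymph node and 0.297 in spleen, against 0.289 in the simulation. The simulated spread was the residual of the additive model, which holds any difference of the transfer effects between tissues. The simulation therefore gives no level without effect, and no conclusion is drawn from it.

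**Figure D3:**
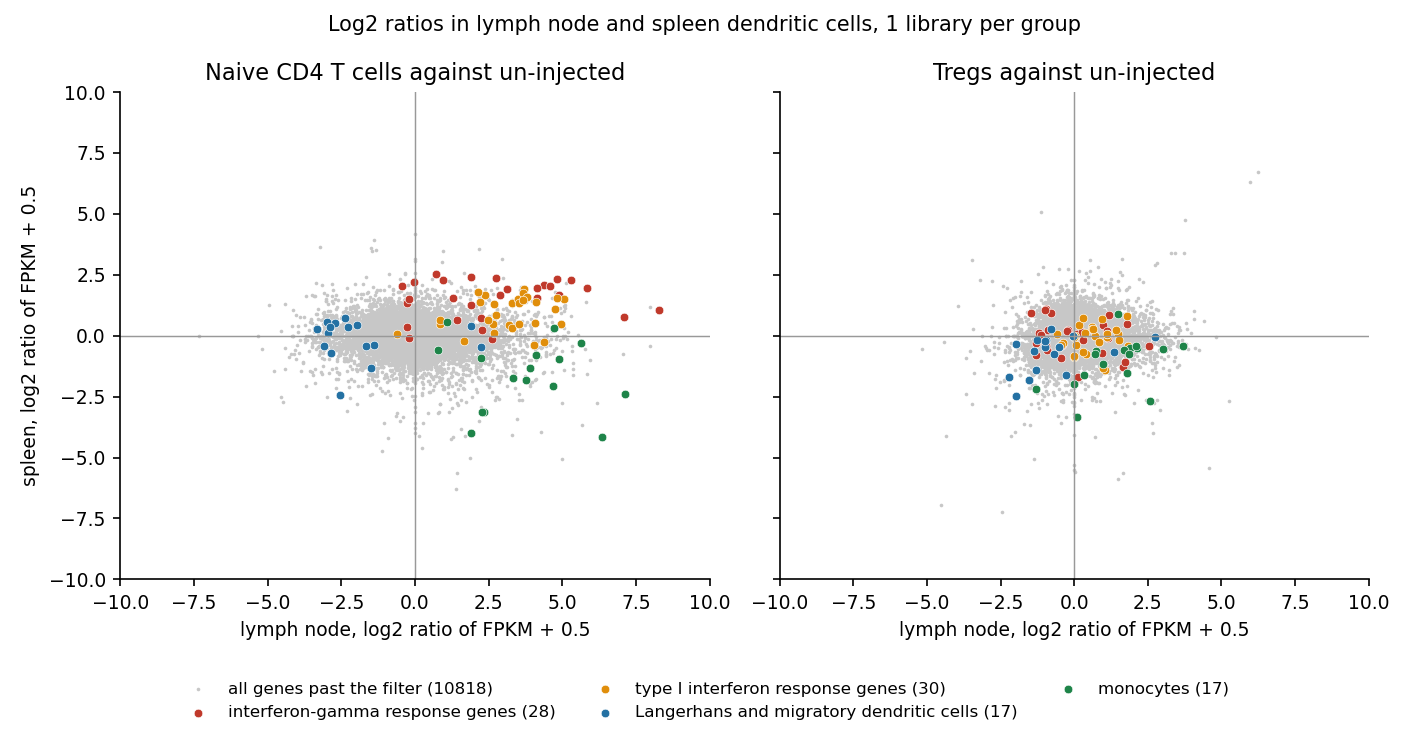
Log2 ratios of FPKM + 0.5 in lymph node (horizontal) and spleen (vertical) for naive over un-injected and for Treg over un-injected, all 10818 genes in grey, interferon-gamma genes in red, type I genes in orange, migratory genes in blue and monocyte genes in green. Most interferon response genes lie in the upper right for naive over un-injected, where r over all genes is -0.057.

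The authors' deposited table marks 284 loci at 2-fold or more with a p-value of 0.01 or less for naive against un-injected in lymph node, 198 higher and 86 lower, of which 9 are in the interferon-gamma list, 19 in the type I list and 7 in the monocyte list. In the same authors' deposited table for spleen 8 loci are marked, 0 of them in either interferon list. For Treg against un-injected the authors' deposited tables mark 58 loci in lymph node and 12 in spleen, with 0 in either interferon list, and for naive against Treg 95 in lymph node and 6 in spleen, with 7 and 2 in the interferon-gamma list and 13 and 0 in the type I list. At 2-fold or more with a q-value of 0.1 or less, the authors' deposited tables hold 25, 5 and 10 tested loci in lymph node and 2, 7 and 3 in spleen. These are for naive against un-injected, Treg against un-injected and naive against Treg, in that order. Each comparison sets 1 library against 1, so its p- and q-values do not measure the spread between mice.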

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

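All the tests of explanations below were chosen after the result was seen except those of library scaling and of X-linked genes, which were written down before their values were computed; the differences between tissues were found by comparing list medians and named genes and were not themselves tested.

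The monocyte list moved in opposite directions in lymph node and spleen, with differences of the median log2 ratio (lymph node minus spleen) of 5.22 for naive against un-injected, 2.42 for Treg against un-injected and 2.78 for naive against Treg. For naive against un-injected the 5 genes with the largest such differences were Chil3 at 10.48, Apoc2 at 10.07, Ly6c2 at 9.52, Hp at 9.33 and Clec4e at 8.95. For the same comparison the differences were 5.06 for neutrophils, 2.31 for macrophages, 2.79 for natural killer and innate lymphoid cells, 2.19 for type 1 conventional and 1.79 for plasmacytoid dendritic cells, and 3.30 for endocytic and C-type lectin receptors. For Treg against un-injected they were 1.36 for macrophages, 1.92 for natural killer and innate lymphoid cells, 1.497 for type 1 conventional and 1.59 for plasmacytoid dendritic cells, 1.70 for endocytic and C-type lectin receptors and 1.77 for proliferation. The erythroid and platelet list differed by 1.91 for naive against Treg.

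In the other direction, lower in lymph node and higher in spleen, were the migratory list at -2.81 for naive against un-injected and -2.16 for naive against Treg, and the CD40 and NF-kB target genes at -1.44 for naive and -0.83 for Treg against un-injected. The costimulatory and coinhibitory ligands differed by -0.95 for naive against un-injected and -0.79 for naive against Treg, and the maturation program by -1.47 for naive against Treg. With 1 library per group the spread of such differences between mice is unknown.

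Interferon response genes were higher in the naive library of both tissues. Monocytes among the sorted cells would need a higher monocyte list in spleen too, where its median was -1.32, which argues against them there; in lymph node it was 3.90, with Lyz2 at 4311 against 166 FPKM and Plac8 at 5169 against 104 FPKM, so a share of monocytes or of cells like them may add to the lymph node values. RNA of the transferred T cells as the source is argued against by T cell genes: Cd3d, Cd3e and Cd3g reached at most 0.426 FPKM in the naive libraries, most of them listed at 0, which can be a missing estimate, while Thy1 was at 1.11 and 0.331 FPKM and Cd6 at 0.936 and 1.09 FPKM, beside Gbp2 at 660 and 80.2 FPKM. Other genes of the T cell list were higher. Tcf7 was at 20.7 and 10.4 FPKM and Il7r at 14.005 and 3.72 FPKM in the naive libraries, but both were also present in un-injected mice, which lack T cells, at 93.7 and 4.496 FPKM and at 68.7 and 3.46 FPKM. A small share of T cells is not excluded, as Ms4a4b was at 18.9 against 0.734 FPKM and Cd2 at 3.94 against 1.21 FPKM in the naive and un-injected lymph node libraries, and in spleen Cd4 at 46.9 against 19.6 FPKM and Tcf7 at 10.4 against 4.496 FPKM. Under both other scalings the interferon-gamma median was at least 1.70. Those scalings moved the median of all genes by -0.04 to 0.35, too little to undo it, so that outcome was fixed in advance. A scaling moves all genes of a library together, while the list lay at percentile 100 of random lists in both tissues, which argues against scaling alone. Of the 17 monocyte genes 4 are also in lists of other cell types or responses, and the gate of the sort is not stated. A response of dendritic cells to the transferred naive T cells stays open as a hypothesis, as does any difference of cage or preparation, since each group holds 1 library.

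Maturation genes were highest in the un-injected lymph node library. A greater share of migratory dendritic cells there is a candidate explanation: the migratory list had a median of -2.55 for naive against un-injected, while those of both conventional subsets lay above 0 in both transferred lymph node libraries. Since 7 of its 17 genes are also maturation genes, the 10 others were looked at alone, and their median was -2.17, with 8 of 10 lower. The un-injected library as the whole source is argued against by the maturation median of naive against Treg, which leaves it out and was -1.10. A change in state of the same cells was not tested, and 1 library per group leaves differences of dissection or sorting open.

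The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in both Treg libraries, at 4.72 to 58.3 FPKM. RNA of transferred male Treg is argued against by Cd3d, Cd3e, Cd3g and Foxp3, which reached at most 1.37 FPKM in those libraries. Most of the Cd3 values are listed at 0, but Foxp3 at 0.673 and 0.4 FPKM, Lck at 0.813 and 0.238 FPKM and Thy1 at 0.523 and 0.937 FPKM were listed above 0 in both and far below Ddx3y, at 36.9 and 52.4 FPKM. Not all genes of the T cell list were so low: Tcf7 was at 60.2 and 6.33 FPKM, Il7r at 62.1 and 2.64 FPKM and Cd4 at 13.2 and 47.6 FPKM, against 93.7 and 4.496, 68.7 and 3.46, and 5.28 and 19.6 FPKM in un-injected mice, so a small share of Treg is not excluded. Male recipients in the Treg groups and female recipients in the others would lower X-linked genes that keep a second active copy in females, and the median of 4 such genes was -1.07 in lymph node and -0.31 in spleen, which is consistent with it. The same 4 genes also had a median of -0.44 in the naive lymph node library, where the Y-linked genes were listed at 0, so the test is weak. In the Treg libraries Eif2s3y, at 58.3 and 39.5 FPKM, lay above its X-linked counterpart Eif2s3x, at 21.8 and 19.5 FPKM. Ddx3y lay below Ddx3x, at 154 and 166 FPKM. If the recipients differed in sex, Treg and sex cannot be separated in these 6 libraries. That limit covers each comparison with Treg, the interferon lists of naive against Treg included.

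For lymph node against spleen, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 74 genes, 1 of 10 splits gave as many, itself included, and the highest of the others gave 0. Each other split mixes the tissues, so the tissue effect enters the residual of its fit. Low counts there were likely in advance, and no conclusion is drawn from them.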

How the results depend on the processing

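The pseudocount of 2 FPKM in limma, the interferon list counts under other settings and the fry test were chosen after seeing the data; the cause of the changes given here was not tested unless stated. The DESeq2, edgeR and count-based alternatives were not run, since the values are not counts, and without counts statements on low genes are limited. No paired analysis was possible because each group holds 1 library and the labels pair no mice; tissue was a block in the model. Leaving out a library leaves 1 residual degree of freedom and a transfer state with a lone library, assumed to vary like the others.

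Genes passing for lymph node against spleen (74) numbered 23 with library totals, 22 with a filter at 5 FPKM, 38 with a pseudocount of 2 FPKM, 311 without the transfer term and 0 with no filter, where more genes are tested. Treg against un-injected and naive against Treg gave 2 each with a pseudocount of 2 FPKM, against 0. Leaving out each library gave 0 to 1557 genes for the tissues, 0 to 425 for naive and 0 to 42 for Treg against un-injected, and 0 to 134 for naive against Treg. Counts adjusted over the list alone, naive against un-injected, were 1 for interferon-gamma without the tissue term and 26 for type I with library totals; leaving out each library gave 13 to 19 and 10 to 27. For naive against Treg they were 0 in both lists without the tissue term and 12 for type I with no filter; leaving out each library gave 0 to 23 and 0 to 28.

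Genes at 2-fold or more fell in number with a filter at 5 FPKM or a pseudocount of 2 FPKM, which remove or shrink low genes: 636 and 539 for naive against un-injected in spleen, 1309 and 1195 for Treg in lymph node, 605 and 472 for Treg in spleen, 1448 and 1382 for naive against Treg in lymph node, and 390 and 291 in spleen. In the last case there were 1290 with no filter and 1357 by the authors' fold changes.

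Lists apart the same way in both tissues for naive against un-injected numbered 3 with a filter at 5 FPKM, against 5. With it the T cell list, Treg against un-injected in spleen, turned from -0.55 to 0.058, with fewer genes. Correlations between tissues became -0.028 (naive) and 0.115 (Treg) with library totals, 0.122 (Treg) and 0.258 (naive against Treg) with the filter at 5 FPKM, and 0.234 (naive against Treg) with a pseudocount of 2 FPKM. Lymph node naive with spleen Treg became -0.089 with totals and -0.128 with the filter, and lymph node Treg with spleen naive 0.014 with totals. Within lymph node r was 0.703 with the pseudocount and 0.716 with the filter, and within spleen 0.613 with totals, 0.664 and 0.654.

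The named transfer genes were taken at 2-fold or more the same way in both tissues, which left their direction little room to turn. None turned under other settings or on leaving out a library, and no conclusion is drawn from that. None of them passed the limma threshold in the main setting. Under other settings 416 of their values did not pass either, and 4 did. Of named tissue genes 89 values still passed under other settings and 51 no longer did, and on leaving out a library 80 still passed and 40 no longer did.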

Other observations

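The explanation of Fkbp5 in the last paragraph was tested with a list written down after Fkbp5 was seen to be higher and before the list's values were computed; the other values are descriptions.

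Among Toll-like receptors, Tlr9, a receptor for bacterial DNA, was at 7.50 FPKM in the un-injected, 44.7 FPKM in the naive and 16.3 FPKM in the Treg lymph node library, and at 7.59, 13.5 and 11.5 FPKM in spleen. Tlr7, a receptor for single-stranded RNA, was at 0.611, 22.6 and 5.16 FPKM in lymph node and at 18.8, 32.1 and 31.9 FPKM in spleen. Of glucose metabolism, Slc2a1, the main glucose importer, was at 8.67, 56.4 and 16.3 FPKM in lymph node and at 19.8, 27.0 and 29.6 FPKM in spleen, and Hk2, a hexokinase, at 2.001, 16.9 and 12.04 FPKM and at 5.68, 12.6 and 10.95 FPKM. Of genes linked to tolerance, Ahr, the aryl hydrocarbon receptor, was at 10.8, 29.5 and 29.3 FPKM in lymph node and at 35.6, 63.4 and 72.0 FPKM in spleen.

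Genes of other cell types also differed between libraries. Slc40a1, the iron exporter of red pulp macrophages, was at 7.90, 1.82 and 1.24 FPKM in the un-injected, naive and Treg lymph node libraries and at 26.0, 9.74 and 12.5 FPKM in spleen. Spic, a transcription factor of these macrophages, was at 28.0, 12.9 and 13.8 FPKM and at 29.0, 14.3 and 16.7 FPKM. Fabp4, a fatty acid binding protein of fat cells and macrophages, was at 27.0, 7.46 and 7.14 FPKM and at 11.7, 5.50 and 4.34 FPKM, and fell adjusted over the list alone in both transfers (1 of 3 genes, 0 over all genes). For adipocytes the fry adjusted p was 0.0156 with naive T cells and 0.498 with Treg, and the former became 0.063 to 0.67 on leaving out any 1 library. Tcf4, a transcription factor of plasmacytoid dendritic cells, was at 26.3, 26.3 and 63.6 FPKM in lymph node and at 8.87, 14.7 and 16.8 FPKM in spleen. Clec10a, a lectin of type 2 conventional dendritic cells, was at 16.0, 91.0 and 210.0 FPKM in lymph node and at 73.3, 32.3 and 55.0 FPKM in spleen.

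Fkbp5 was higher in both Treg libraries and is induced by glucocorticoids, so a glucocorticoid response was a candidate explanation. Of 8 other glucocorticoid response genes the median log2 ratio of Treg to un-injected was 0.067 in lymph node (standard error of the median 0.495), with 4 of 8 genes lower, and 0.275 in spleen (0.172) at percentile 98.8, with 2 of 8 lower. Both lie under the 0.5 set in advance as the bound against it, in lymph node by less than the spread of the genes, which was set beside the bound only after the medians were seen. The median of naive to Treg was -0.33 in lymph node at percentile 4.96 and -0.41 in spleen at percentile 0.18. A glucocorticoid response therefore stays open.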
